A study of Mus musculus with 6 samples.

How the data were processed

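The series measured where the histone variant H2A.B and 5-methylcytosine (5mC) lie in the genome of mouse embryonic stem (ES) cells of the C57Bl/6 strain, which were grown with leukaemia inhibitory factor (LIF) and without feeder cells. H2A.B is a short variant of histone H2A, also called H2A.Bbd. It was recovered by chromatin immunoprecipitation (ChIP), in which crosslinked chromatin is sheared and pulled down with an antibody, here a rabbit antibody made by the submitters. 5mC was recovered by methylated DNA immunoprecipitation (MeDIP), in which sheared, denatured DNA is pulled down with an antibody against the methylated base. Each assay had 1 library made with IgG, a non-specific antibody that measures background. The 6 libraries were 1 of H2A.B ChIP, 1 of IgG ChIP, 3 of 5mC MeDIP and 1 of IgG MeDIP. Per the labels' protocols, ChIP fragments of 200 to 400 bp were amplified with 20 PCR cycles and MeDIP fragments of 100 to 400 bp with 15. The labels do not say whether the 3 5mC libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. For both IgG libraries 1 label field names the H2A.B antibody while the title and the antibody field give IgG. The title and the antibody field were used.

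Each deposited file is a list of aligned reads, with chromosome, start, end, read name, a score and a strand. The score column as deposited by the authors is constant and was not used. The reads were aligned with Bowtie to build mm9 and checked with FastQC, per the submitters' processing notes, which name these tools without versions. The alignment settings, and whether reads with several matches were kept, are not given in the sources used here. Flow cell and lane were taken from the first read name of each list only. Reads of H2A.B ChIP and 5mC replicate 1 were 42 bp long and came from lane 3 of 1 flow cell. Those of 5mC replicate 2 and IgG MeDIP were 50 bp long and came from lane 1 of a second flow cell, and those of 5mC replicate 3 and IgG ChIP were 50 bp long and came from lane 2 of it. H2A.B and its IgG control therefore differ in flow cell and read length as well as in antibody, and batch and group cannot be told apart for that comparison. 5mC replicates 2 and 3 share a flow cell and read length with IgG MeDIP.

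The lists of H2A.B and of 5mC replicate 1 held 1 and 8 lines without the tab format of the rest, and these 9 lines were left out. All 201263 reads of IgG MeDIP were also present in the list of 5mC replicate 2, with the same names and positions, and were removed from replicate 2. A further 2979 reads of that list had a blank strand.

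Reads were counted once per chromosome, 5′ position and strand, because the libraries were amplified by PCR and carried no molecular identifiers. Distinct reads were counted in 100 kb windows on chromosomes 1 to 19, X and Y and normalised to the total of distinct reads on those chromosomes (CPM). Windows were left out where the mean CPM of the 6 libraries was under 25% of the median over windows (770 windows), or where any library exceeded 10 times its own median (81 windows, as collapsed repeats). This left 25576 of 26427 windows. Coordinates are those of mm9 and count from 1. No mm9 sequence or annotation was used here, so no gene was placed, and the planned counts over promoters, gene bodies and gene lists and the correction for base composition were not made.

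Agreement between libraries was described with Spearman's rho and Pearson's r of log2 CPM across windows, with a pseudocount worth 0.5 reads in IgG MeDIP. Windows are not independent replicates and no p was computed from them. 5mC was compared with IgG MeDIP by limma with an intensity trend (two-sided, Benjamini-Hochberg threshold 0.05). The single IgG library was assumed to vary like the 5mC libraries. On simulated data this test, as first planned at unequal depths, called 10151 unchanged windows. The 5mC libraries were therefore thinned at random to the depth of IgG MeDIP, a change made after the data were examined. After thinning, 0 unchanged windows were called, and the test recovered 0% of 100 windows raised 4-fold and 21% of 100 windows raised 16-fold. In 1 Mb windows it recovered 90% of 100 windows raised 2-fold, with 5 unchanged windows called among 2577. The simulated counts held counting noise around a shared mean, without spread between replicates or regional differences between libraries. Recovery and false calls in the deposited libraries may therefore be worse.

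H2A.B had no replicate, so a rule of size was used. A window counted as enriched where the CPM ratio of H2A.B to IgG ChIP was at least 1.5 and its exact 95% lower bound (Clopper-Pearson, from the binomial share of the reads of both libraries) was above 1. The mirrored rule, with the libraries exchanged, counted windows by the same measure in the opposite direction. On simulated data the rule recovered 85% of 100 windows raised 2-fold. The rule and the mirrored rule together called 865 unchanged windows of 25576. These counts too were simulated with counting noise alone, so regional differences between the libraries could add false calls. All intervals cover counting error only. The relation between H2A.B and 5mC was the Spearman rho across windows of the log2 ratio of H2A.B to IgG ChIP with that of each 5mC library to IgG MeDIP, set against 1000 circular shifts along each chromosome. Local maxima of H2A.B were 1 kb windows with at least 10 distinct reads and at least 4 times the mean of their 100 kb window. Reads at them were divided by those in flanks 5 to 10 kb away.

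The windows named are the 10 highest by the lower bound of the H2A.B ratio, the 10 lowest by its upper bound, the 5 highest and 5 lowest for 5mC by the limma statistic, the 5 with most local maxima, with adjacent windows merged and counted once, and chromosomes X, Y and M with the autosomes of highest and lowest ratio. This rule, the groups, the tests and most alternatives were fixed before the data were examined. The alternatives were windows of 10 kb and 1 Mb, all reads as deposited, no filter, autosomes, pseudocounts of 0.1 and 2 reads, median centring, H2A.B ratios of 1.2 and 2, a correlation without division by IgG, a partial correlation, other thresholds and flanks for local maxima, and leaving out each 5mC library in turn. Alternatives chosen after seeing the data were the untouched and the shortened list of 5mC replicate 2, the limma test at unequal depths, a partial correlation without division by IgG, and centring within 5 Mb segments. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1 were used.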

Results

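Aligned reads were available for 1 H2A.B ChIP library, 1 IgG ChIP library, 3 5mC MeDIP libraries and 1 IgG MeDIP library of mouse ES cells. H2A.B ChIP held 9266471 reads, of which 86.9% lay at distinct positions, and IgG ChIP held 811727, of which 68.2% were distinct. The 5mC libraries held 3503839 reads (39.9% distinct) in replicate 1, 4180959 (47.1%) in replicate 2 and 1574706 (52.5%) in replicate 3. IgG MeDIP was the smallest, with 201263 reads and 64.2% distinct. The median 100 kb window held 279 distinct reads of H2A.B, 19 of IgG ChIP, 40, 60 and 29 of 5mC replicates 1, 2 and 3, and 3 of IgG MeDIP. In IgG MeDIP 2180 of the 25576 windows held no read, and a count of 0 there allows up to 24.2 CPM, the level of its median window. H2A.B, IgG ChIP and IgG MeDIP had no replicates.

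A few repeat regions took a large share of the 5mC reads, among them places of mm9 known to collect reads of satellite DNA. The region at chromosome 2, 98500001 to 98510000, held 16.3% ± 10.7 (SD, n = 3) of the deposited 5mC reads, and that at chromosome 9, 3000001 to 3040000, held 13.5% ± 4.03 (SD, n = 3). IgG MeDIP had 14.9% and 15.3% of its reads at the same places, from which the 5mC means differed by less than the spread between replicates. Replicate 1 stood above IgG MeDIP at both places, at 27.9% and 16.6%. In H2A.B ChIP the shares were 4.25% and 3.42%, against 5.64% and 6.69% in IgG ChIP. Over the 8 regions that exceeded 0.2% of the reads of a library, the share was 33.8% ± 16.8 (SD, n = 3) for 5mC, 34.3% for IgG MeDIP, 8.63% for H2A.B and 13.8% for IgG ChIP. The 5mC replicates spread from 17.3% to 50.9%.

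The first comparison asked how closely the 5mC libraries resembled one another and their background. Across windows Spearman's rho was 0.768 between replicates 1 and 2, 0.597 between replicates 1 and 3 and 0.693 between replicates 2 and 3, with Pearson's r of 0.756, 0.590 and 0.696. IgG MeDIP correlated with the same replicates at rho 0.589, 0.740 and 0.541. Replicate 2 was thus closer to IgG MeDIP than to replicate 3. The H2A.B profile correlated with 5mC replicates 1, 2 and 3 at 0.779, 0.801 and 0.640, above its value of 0.560 with IgG ChIP, which had fewer reads per window than any 5mC library. In 1 Mb windows the highest values were 0.939 between 5mC replicate 2 and IgG MeDIP and 0.918 between 5mC replicate 3 and IgG ChIP, pairs that shared a sequencing lane, followed by 0.900 between H2A.B and 5mC replicate 1, which shared the other flow cell.

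The second comparison asked which regions carried 5mC above the IgG background. No 100 kb window passed the test in either direction. With limma, 0 windows were higher and 0 lower in 5mC than in IgG MeDIP, with a smallest adjusted p of 0.578, while 1605 were higher and 144 lower at an unadjusted p under 0.05. The 5 windows with the highest limma statistic lay at chromosome 10, 74200001 to 74300000, chromosome 5, 31100001 to 31200000, chromosome 12, 25800001 to 25900000, chromosome 18, 45500001 to 45600000, and chromosome 1, 119100001 to 119200000. IgG MeDIP had no read in any of them, and 5mC was at 45.7 ± 13.6, 54.1 ± 5.40, 43.9 ± 9.16, 28.3 ± 6.34 and 31.1 ± 5.59 CPM (SD, n = 3). The lowest were chromosome 16, 5700001 to 5800000, chromosome 1, 158900001 to 159000000 and 72600001 to 72700000, chromosome 7, 50200001 to 50300000, and chromosome 8, 88000001 to 88100000, with 14 to 25 IgG reads. At full depth the first of these held 65.6 ± 22.5 CPM of 5mC (SD, n = 3) against 201 CPM of IgG MeDIP, and the last 54.8 ± 4.44 against 113. The test itself used thinned libraries, in which the log2 differences were -1.97 and -1.81. At this depth a difference of 4-fold in a window was not detectable. False calls of the test in 10 kb windows were not simulated, and there the upper filter was applied to H2A.B alone. Counts at that window size can therefore not be read as gain or loss of 5mC. In 10 kb windows 77 were higher and 16629 lower, and without the filter 13 were lower.

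The third comparison asked where H2A.B lay relative to IgG ChIP. By the rule of size 2474 windows (9.67%) were enriched for H2A.B, and the mirrored rule gave 2415 (9.44%). Scaling each library to its total sets the centre of the ratios near 1, so the balance of the 2 counts is no measure of how much H2A.B was recovered. The balance moved with window size, to 1532 and 6737 in 10 kb windows and 126 and 203 in 1 Mb windows. The median ratio over windows was 1.01, with a 10th percentile of 0.618 and a 90th of 1.64. Enriched windows were unevenly spread. Chromosome X had 262 enriched windows and 18 in the mirrored direction, chromosome 17 had 153 and 54, and chromosome 19 had 85 and 13. Chromosome 1 had 45 enriched windows and 698 in the mirrored direction, chromosome 11 had 24 and 188, and chromosome 8 had 34 and 222. This compares 2 libraries, not conditions, with no replicate check. With each ratio divided by the median of its 5 Mb segment, 1140 windows were enriched and 1322 mirrored.

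Among the 10 windows with the highest lower bound, 3 lay on chromosome X. The first was chromosome 17, 24000001 to 24100000, with 480 H2A.B and 5 IgG reads and a ratio of 6.43 (95% interval 2.74 to 19.9). Chromosome X, 7400001 to 7500000, had 465 and 5 reads and a ratio of 6.23 (2.65 to 19.3), and chromosome 5, 37600001 to 37700000, had 508 and 7 reads and a ratio of 4.86 (2.34 to 12.1). At chromosome 13, 74600001 to 74700000, the depth was greatest, with 1521 and 33 reads and a ratio of 3.09 (2.19 to 4.5). The others were chromosome 6, 113900001 to 114000000, chromosome X, 70900001 to 71000000 and 102900001 to 103000000, chromosome 15, 101500001 to 101600000, chromosome 5, 114200001 to 114300000, and chromosome 7, 151700001 to 151800000. Among the 10 lowest, chromosome 2, 22400001 to 22500000, had 357 H2A.B and 103 IgG reads and a ratio of 0.232 (0.186 to 0.292). Chromosome 7 held 3 of them, at 33200001 to 33400000 (adjacent windows merged), 26800001 to 26900000 and 32500001 to 32600000, with ratios of 0.198, 0.177 and 0.197. The other 6 were chromosome 4, 64100001 to 64200000, chromosome 5, 15100001 to 15200000, chromosome X, 139900001 to 140000000, chromosome 6, 132400001 to 132500000, chromosome 1, 148300001 to 148400000, and chromosome Y, 700001 to 800000, with ratios up to 0.278.

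Windows enriched for H2A.B also held more reads of the MeDIP libraries. In the 2474 enriched windows mean CPM was 1.54 ± 0.456 (SD, n = 3) times that of the 20687 windows called in neither direction for 5mC, with 2.05 in replicate 1, 1.41 in replicate 2 and 1.17 in replicate 3. IgG MeDIP was raised 1.46-fold in the same windows, within the spread of the 5mC libraries. In the 2415 mirrored windows the 5mC mean stood at 0.899 ± 0.166 (SD, n = 3) and IgG MeDIP at 0.949. Replicates 1, 2 and 3 stood at 0.734, 0.897 and 1.07 there, so replicate 3 was raised in both sets. The windows were chosen on the ratio of H2A.B to IgG ChIP. Relative to windows called in neither direction, H2A.B stood at 1.62 and IgG ChIP at 0.880 in the enriched windows. In the mirrored windows they stood at 0.686 and 1.33.

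The fourth comparison asked whether H2A.B and 5mC shared regions. After division by the IgG library of each assay, rho across windows was 0.112 for 5mC replicate 1, -0.0392 for replicate 2 and -0.196 for replicate 3, a mean of -0.0410 ± 0.154 (SD, n = 3). The 1000 circular shifts, which keep differences between chromosomes and are not centred on 0, gave 0.00839 to 0.0575 for the mean, all above the observed mean. They gave 0.0334 to 0.0936 for replicate 1, -0.00240 to 0.0416 for replicate 2 and -0.0304 to 0.0505 for replicate 3. The observed value lay above all shifts in replicate 1 and below all shifts in replicates 2 and 3, and the replicates differed in sign. With the first block of the replicate 2 list alone, its rho was -2.26e-05, inside the range of the shifts for the whole list. Replicate 1, the positive value, shared a lane with H2A.B, and replicate 3, the most negative, shared a lane with IgG ChIP, by which H2A.B was divided. Antibody and batch cannot be told apart in these values or their mean. Without division by IgG, rho was 0.740 ± 0.0872 (SD, n = 3), and the same value for H2A.B with IgG MeDIP was 0.612. IgG MeDIP held 3 reads in the median window, against 29 to 60 in the 5mC libraries. No undivided value at equal depth was computed, so the gap cannot be read as specific to 5mC.

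At a finer scale, 7513 windows of 1 kb were local maxima of H2A.B, in 6081 of the 100 kb windows. The 5mC libraries had 8.48 ± 2.75 (SD, n = 3) times as many reads there as in the flanks, with 8.85, 11.03 and 5.57 in replicates 1, 2 and 3. IgG MeDIP had 16.5 times as many (95% interval 15.9 to 17.2), above each 5mC library, and IgG ChIP 4.63 times (4.51 to 4.76). H2A.B itself, on which the maxima were chosen, stood at 6.21. No test was made of these folds. With maxima of IgG ChIP left out, 6153 remained, and the folds were 5.63 ± 2.24 (SD, n = 3) for 5mC and 8.53 for IgG MeDIP. The most maxima lay at chromosome X, 131500001 to 131600000, with 12, and chromosome 16, 3200001 to 3300000, with 10, followed by 9 each at chromosome 5, 33000001 to 33100000, chromosome 7, 66900001 to 67000000, and chromosome 8, 56200001 to 56300000. Conversely, at 28426 maxima of the summed 5mC libraries H2A.B stood at 2.36 and IgG ChIP at 3.48 times the flanks. IgG MeDIP stood at 14.2 there, above the 8.42, 12.2 and 4.63 of the 5mC libraries on which these maxima were chosen.

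**Figure D1:**
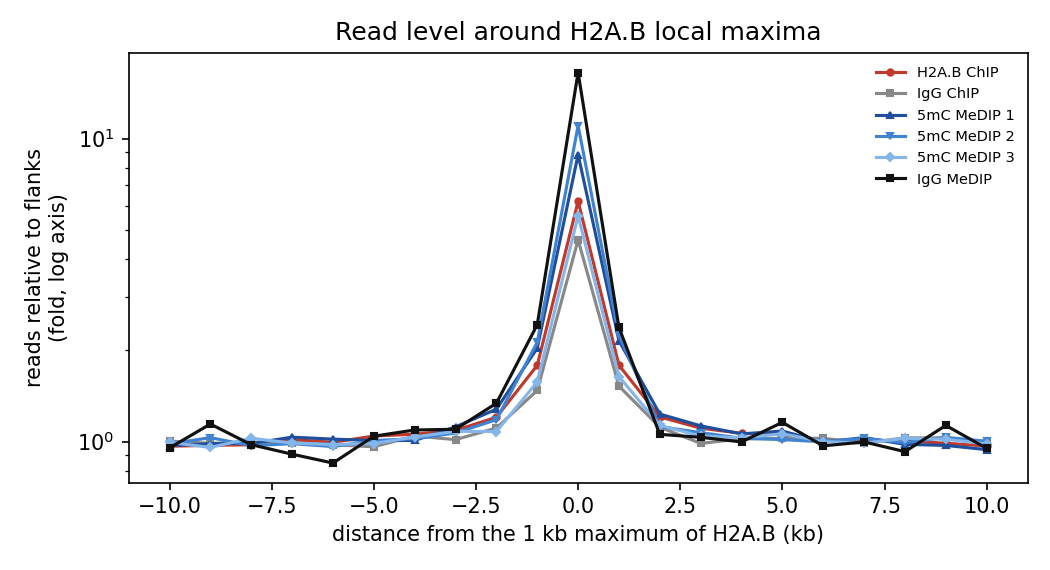
Distinct reads per 1 kb around the 7513 local maxima of H2A.B, relative to the flanks 5 to 10 kb away (fold, log axis), against the distance in kb, with 1 line per library. At distance 0 IgG MeDIP stands highest at 16.5, the 5mC libraries lie between 5.57 and 11.03, and IgG ChIP stands at 4.63.

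The last comparison concerned whole chromosomes. As a ratio of shares of distinct reads, H2A.B to IgG ChIP was 1.30 (95% interval 1.28 to 1.32) on chromosome X, 0.374 (0.333 to 0.422) on chromosome Y and 0.122 (0.115 to 0.130) on the mitochondrial genome. With all reads as deposited, chromosome Y stood at 0.701. Among autosomes the lowest ratio was 0.754 (0.747 to 0.762) on chromosome 1 and the highest 1.16 (1.14 to 1.18) on chromosome 19. Chromosome 9 stood at 0.757 with its satellite region and at 1.09 in the windows kept. The ratio of 5mC to IgG MeDIP was 1.53 ± 0.204 (SD, n = 3) on chromosome X, 0.733 ± 0.120 on chromosome Y (1.05 ± 0.196 in the windows kept) and 0.865 ± 0.350 on the mitochondrial genome. Chromosome X relative to autosomes, over kept windows, was at 0.690 in H2A.B, 0.544 in IgG ChIP, 0.509 ± 0.0707 (SD, n = 3) in 5mC and 0.356 in IgG MeDIP.

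Several chromosomes differed between libraries of the same assay. Relative to the median autosome, chromosome 8 was at 1.04 in H2A.B and 1.07 in 5mC replicate 1, and at 1.36, 1.2, 1.26 and 1.43 in 5mC replicates 2 and 3, IgG ChIP and IgG MeDIP. Chromosome 11 was at 1.19 and 1.23 in the first pair and at 1.41, 1.42, 1.43 and 1.5 in the others. Chromosome 1 was at 0.841 and 0.816 in the first pair and at 1.11, 1.2, 1.2 and 1.16 in the others. The first pair came from the flow cell with 42 bp reads, and the others from the second flow cell. The ratios of H2A.B to IgG ChIP on these and all other chromosomes, X, Y and M included, therefore compare libraries that also differ in flow cell and read length. On chromosome X, H2A.B stood at 0.681. 5mC replicate 1 stood at 0.536 there, within the 0.371 to 0.569 of the libraries of the second flow cell, so chromosome X did not follow this split. On chromosome Y, with 24 kept windows, H2A.B stood at 0.191, 5mC replicate 1 at 0.430 and the libraries of the second flow cell at 0.472 to 0.635. On the mitochondrial genome IgG ChIP stood apart from all other libraries, with 0.281% of its distinct reads. H2A.B had 0.0344% there, and the 5mC and IgG MeDIP libraries 0.0227% to 0.0538%.

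**Figure D2:**
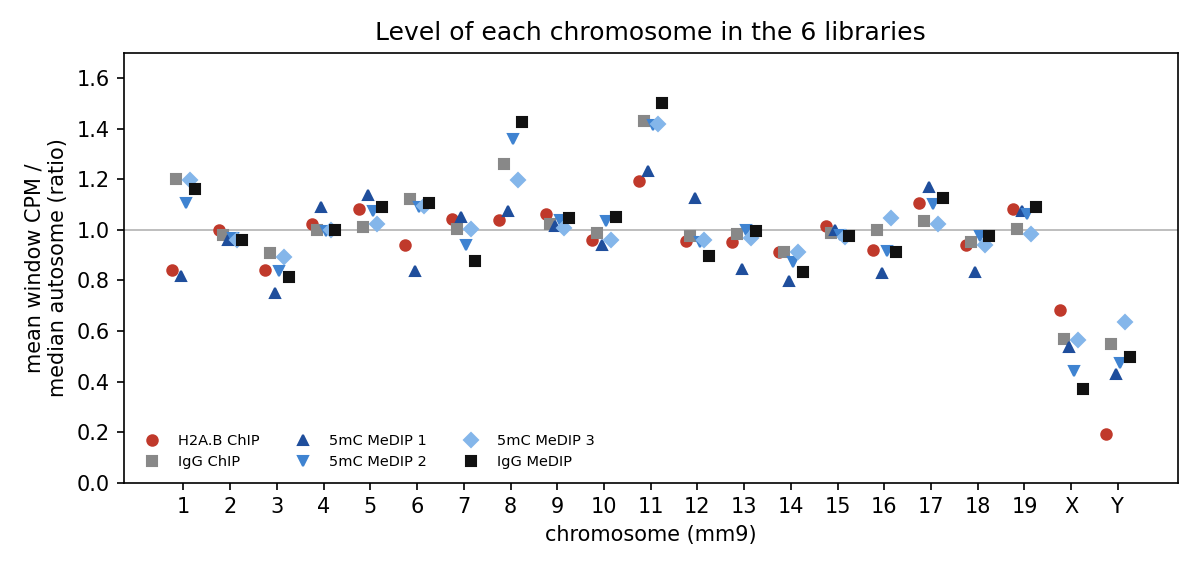
Mean CPM of the kept windows of each mm9 chromosome relative to the median autosome (ratio), with 1 point per library. On chromosomes 1, 8 and 11 H2A.B and 5mC replicate 1 lie below the other 4 libraries, at 0.841 and 0.816 against 1.11 to 1.2 on chromosome 1.

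**Figure D3:**
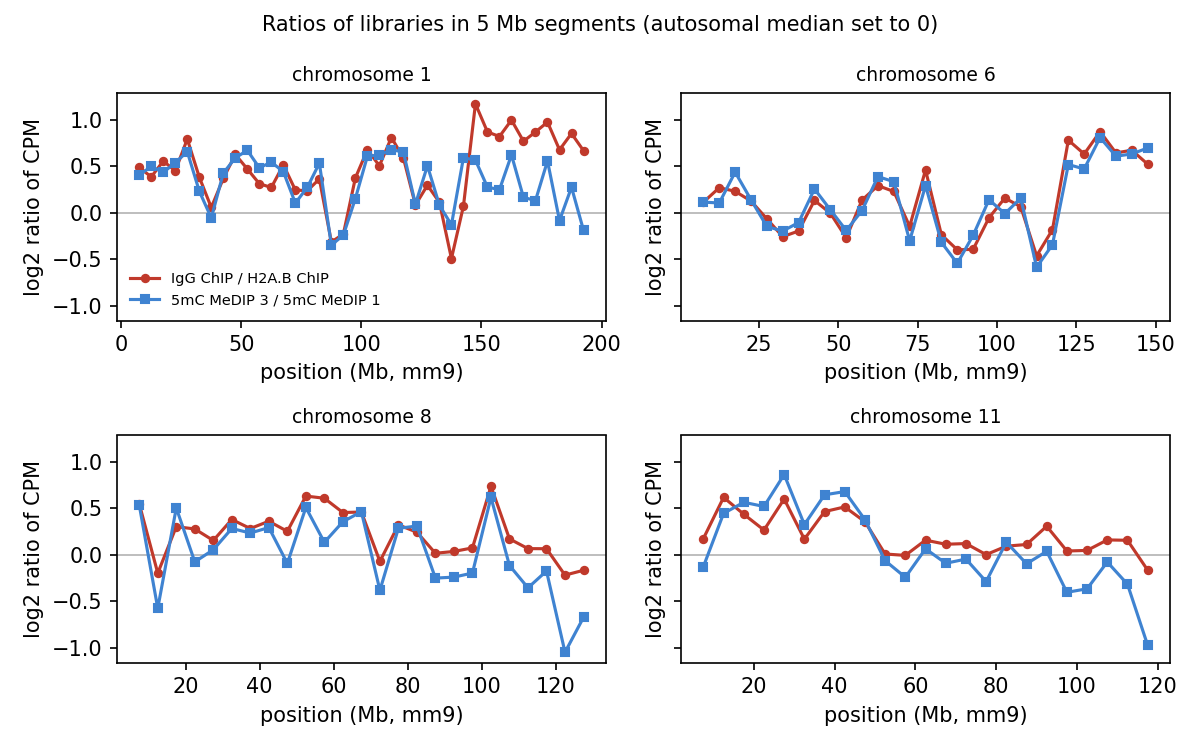
Log2 ratio of CPM of IgG ChIP to H2A.B and of 5mC replicate 3 to 5mC replicate 1 in 5 Mb segments of chromosomes 1, 6, 8 and 11, against position in Mb, with the autosomal median set to 0. The ratios share no library but compare the same pair of lanes, and over 474 autosomal segments they correlate at rho 0.852.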

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

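The tests of this part were chosen after the patterns had been seen, except that on the chromosomes after regression, whose outcome was predicted before it was run.

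Every IgG MeDIP read was also in the list of 5mC replicate 2, which drew attention as signal in reads that the comparisons leave out. The replicate 2 list consisted of 4 blocks, each sorted on its own, of 2269446, 1538401, 201263 and 373112 reads, and all 201263 shared reads formed the third. A candidate explanation is that several read lists were joined when the file was made, one of them the IgG list, and the single contiguous block has the form this needs. A draw of IgG reads from the same amplified library is argued against, because the positions of the IgG block recurred in any other block at no more than 0.0605 times the rate of a random draw of the same size (1.84% against 30.4% in the first block). Which of the other blocks belong to replicate 2 stays open, and no biological explanation was tested.

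Regional levels differed between the libraries with 42 bp reads (H2A.B and 5mC replicate 1) and those with 50 bp reads. A regional bias, such as base composition or chromatin accessibility, may account for part of this. Ratios that share no library correlated at rho 0.856 over 5 Mb segments of autosomes other than 1, 6, 8 and 11. Both ratios compare the same pair of lanes, so any regional difference between those lanes would give this correlation, whatever its source. After regression on the H2A.B level and the ratio of 5mC replicate 1 to H2A.B, chromosomes 8 and 11 still stood above prediction in IgG ChIP. The excess was 0.30 (0.297) and 0.44 log2 units, in 25 of 25 and 23 of 23 segments, while 15 other autosomes lay between -0.05 and 0.07. In IgG MeDIP it was 0.440 and 0.355, with the others between -0.239 and 0.184. In 5mC replicate 3 it was 0.230 and 0.415, with the others between -0.057 and 0.155. In replicate 2 it was 0.441 and 0.319 in the first block, but -0.038 and 0.024 in the fourth. Flow cell and read length cannot be told apart from this split. The lists placed on the second flow cell, apart from the fourth block of replicate 2, all had chromosome 8 raised (1.2 to 1.44). That block, with chromosome 8 at 1.01, is 1 list of open origin whose flow cell and lane were not read. Its reads were 50 bp long, like all reads of the replicate 2 list, so 1 list of 50 bp reads lacked the excess. Being 1 list of open origin, it does not decide on read length. Extra copies of chromosomes 8 and 11 in the cells of the libraries with 50 bp reads remain a hypothesis found on these data. Chromosomes 1 and 6, left out of the 15, stood 0.38 and 0.17 above prediction in IgG ChIP as well (in 37 of 38 and 16 of 29 segments). Chromosome 1 stood at 0.524 in IgG MeDIP, 0.400 in 5mC replicate 3 and 0.484 in the first block of replicate 2. Each of these, and its value in IgG ChIP, was above that of chromosome 8. The excess was thus not particular to chromosomes 8 and 11. Base composition itself could not be tested without an mm9 sequence.

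The 9 lines without the tab format of their lists, 1 in H2A.B and 8 at the end of 5mC replicate 1, all lay between 150481211 and 150481342 on chromosome 7, which drew attention as signal in lines outside the comparisons. In the correctly formatted lines the 1 kb window from 150481001 held 27 H2A.B reads, of which 8 followed another read of the window at a different position within 2500 lines, against 0.189 expected, and it ranked 1 of 2255111 windows by a Poisson model, which argues against chance in that list. In 5mC replicate 1 it ranked 9 of 732137, with 5 such pairs against 0.656, and chance is not excluded there. In the H2A.B list 0 pairs within that distance shared position and strand. This count was largely fixed in advance, since the 27 reads lay at 26 distinct positions. It does not decide on optical or PCR duplicates. The values for 5mC as the cause follow. Replicates 2 and 3 together held 1 distinct position, where the rate of replicate 1 (26 positions) predicts 35.2 and 15.0. Equal 5mC signal in all replicates is thus argued against. Replicate 1 shared flow cell and read length with H2A.B, which also held 26 positions. IgG ChIP and IgG MeDIP, from the flow cell of replicates 2 and 3, held 0. Antibody and flow cell cannot be told apart here, so the count does not decide on 5mC. The 8 lines at the end of 5mC replicate 1 all carried read names from 1 tile, an area of the flow cell lane. Of these lines, 6 gave the same interval, 150481301 to 150481342. The names of these 6 were identical except for a few digits of 1 coordinate. Whether these lines are sequenced reads was not tested. H2A.B and 5mC at this window, and how the lines came to lie together, stay open.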

How the results depend on the processing

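Of 84 recomputed values, 56 stayed close to the reported value (counts within 1.5 times, other values within the SD of the replicates or, without replicates, the counting interval) and 28 did not; 11 and 11 of the former are counts of 5mC windows, higher and lower, that stayed at 0, most in a test with little power at 100 kb, and say little about stability. The cause was not tested unless given. Mean rho between 5mC libraries (0.686 ± 0.0858, SD of 3 pairs) was 0.373 in 10 kb and 0.853 in 1 Mb windows, and 0.597 to 0.768 with 1 library left out. For the 5mC test that follows, the 10 kb setting was not simulated, so its rate of false calls is unknown. For 5mC against IgG MeDIP, windows higher numbered 4 with median centring, 77 in 10 kb windows and 3665 at unequal depths (added after seeing the data; this setting failed on simulated data), and windows lower 13 without the filter, 16629 in 10 kb windows and 174 at unequal depths. All settings that left out 1 5mC library gave 0 and 0, as did 1 Mb windows, where the smallest adjusted p from limma was 0.0634. Over all settings the smallest adjusted p ranged from 6.39e-15 to 0.993. Windows enriched for H2A.B and windows in the mirrored direction numbered 1532 and 6737 in 10 kb windows, 126 and 203 in 1 Mb windows (fewer windows), 873 and 778 at a ratio of 2, and 1140 and 1322 with centring within 5 Mb segments (added after seeing the data). With all reads as deposited, 4190 were enriched and 2813 mirrored, a share of enriched calls above that of distinct reads, while enriched over mirrored windows, 1.02 as reported, fell below 1 in 10 kb (0.227) and 1 Mb windows (0.621) and with median (0.935) or 5 Mb centring (0.862). The relation of H2A.B to 5mC rose to 0.740 without division by IgG, to 0.530 with a partial correlation given the IgG mean and to 0.624 with centring within 5 Mb segments, the last pair added after seeing the data and also undivided; it was -0.118 to 0.0367 with 1 library left out. The sign of the mean also turned in 10 kb windows (0.0290, positive in 2 of 3 replicates) and with all reads (0.00764), and the partial correlation of the divided values was -0.000275, all within the SD of the reported mean. The 5mC fold at local maxima of H2A.B was 20.7 and 5.51 at 8 and 3 times the local mean, 15.6 with all reads, 5.63 without IgG ChIP maxima and 7.21 to 9.94 with 1 library left out; IgG MeDIP stood above the 5mC mean each time, at 46.3, 10.1, 22.1 and 8.53.

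Planned counts over gene features and gene lists and the correction for base composition were not run without an mm9 annotation and sequence. No paired analysis was possible because the groups share fewer than 2 replicate numbers. The depth of IgG MeDIP, 3 reads in the median window, limits every 5mC ratio, and that of IgG ChIP, 19 reads, every H2A.B ratio.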

Other observations

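The share of distinct reads differed between libraries and between the blocks of the 5mC replicate 2 list. It was 46.0% in the first block, 41.96% in the second and 91.7% in the fourth, against 86.9% in H2A.B and 39.9% in 5mC replicate 1. The fourth block had chromosome X at 0.643 and chromosome Y at 0.225 of the median autosome. H2A.B stood at 0.681 and 0.191, and the first block at 0.394 and 0.514. In H2A.B 53.7% of reads lay on the plus strand, against 42.3% in IgG ChIP, 57.7% in 5mC replicate 1 and 37.7% in replicate 2.

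Some repeat regions took far more reads in libraries of the second flow cell. A region of chromosome 13, 13950001 to 13960000, held 1.58% of the reads of 5mC replicate 2, 1.49% of IgG MeDIP, 0.321% of 5mC replicate 3 and 0.242% of IgG ChIP, against 0.00243% of H2A.B and 0.00425% of 5mC replicate 1. The 1 kb window of chromosome 17 from 63086001 held 130 H2A.B reads and 97 reads of 5mC replicate 1, with 22 and 24 pairs close in file order at different positions against 4.45 and 6.42 expected, and 33 and 23 close pairs that shared position and strand.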
